A study of Mus musculus with 26 samples.

How the data were processed

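The series holds RNA-seq of macrophages sorted from mouse mammary tumours. Per the labels' protocols, PyMT mammary tumour cells were injected into the mammary gland of female FVB mice, and each tumour was excised and weighed. Cells positive for CD11b and F4/80 and negative for Ly6G were collected by flow sorting in the presence of cycloheximide, a drug that holds ribosomes on mRNA. Per the same labels, about 10 percent of the cells of a tumour gave total mRNA, and the rest was lysed and run on a sucrose gradient, from which mRNA carrying at least 3 ribosomes was pooled as the polysome fraction. Both RNA sources were made into libraries with SmartSeq2, a full-length cDNA method that does not mark the strand. The 26 libraries come from 13 tumours in 2 batches. The labels give each tumour's weight, the batch and, in batch 2, titles that divide the tumours into ER and LR. Each tumour is a separate animal sample, so the p-values of single genes and of values per library measure the spread between tumours. Those of gene lists at a preset correlation rest on the genes of a list as well, and do not measure that spread.

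Per the submitters' processing notes, HISAT, HISAT2, limma and the mouse build mm10 were named, with no role or version. The counting tool, the annotation and the strand setting are not given in the sources used here. For each library the authors deposited a table of 19549 gene rows with whole-number read counts per gene and a second column of log2 values. In 830 rows the authors joined the names of overlapping genes into 1 row, whose reads cannot be divided between them. The deposited log2 values cover the 10472 genes with a count of 0 in at most 3 libraries, and they differ from log2 CPM by 1 constant per library, with a largest deviation of 5.1e-14, so they are CPM rescaled per library. The count column was used for every test, and the log2 column was only checked.

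Tumours were divided at 1000 mg into 8 small tumours, of 467 to 841.8 mg, and 5 large tumours, of 1504 to 2245 mg. The limit falls in the gap of the weights, and the ER and LR tumours of batch 2 lie on either side of it. Small replicates 1 to 5 and large replicates 1 and 2 are batch 1. Small replicates 6 to 8 (ER) and large replicates 3 to 5 (LR) are batch 2. Total counts were 18018519 to 55609113 in total mRNA libraries and 7034173 to 28257436 in polysome libraries.

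Genes were filtered with filterByExpr on the groups of each fit, scaled with TMM and tested with the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Size was tested within each RNA source with batch as a covariate. Translation was tested as the interaction of RNA source and size class in 1 fit over the 26 libraries, with the tumour as a block and RNA source by batch as a term. The same fit gave polysome against total mRNA. The labels take both libraries of a tumour from 1 sorted population, which is where the pairing comes from. The deviations of both libraries from their group means had a median correlation of 0.249 within a tumour (lowest 0.0372) and −0.0167 between tumours. Each batch was also fitted alone, and a size by batch term was fitted for each size comparison. A fold is positive where it is higher in large tumours or in polysomes. Levels are TMM-scaled CPM as mean ± SD over tumours, and differences of polysome and total mRNA per tumour used log2 CPM with a prior count of 1.

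The 31 gene lists held pathways, translation classes, RNA quality sets and cell type markers, of resident-type macrophages and of other cells. Members were tested as a set with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of 1 comparison, for lists with at least 3 genes. That left 27 lists in the total mRNA, translation and polysome against total comparisons and 26 in polysome mRNA. Camera compares the members with all other genes. In the main fits it was repeated with a correlation estimated from the residuals, and fry tested whether the members moved on balance one way. Of the lists not tested, that of mitochondrially encoded mRNAs had 0 members in the tables, nuclear-retained non-coding RNAs had 1, B cell markers had 10 and erythroid markers had 3 with too few of them past the filter. Further sets of 18 gene families were formed by symbol after the data had been examined.

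Named genes followed a fixed rule. Where genes passed the threshold, these were the 12 in each direction with the largest fold among those with a mean of at least 10 CPM and the same sign in both batches alone, leaving out unnamed predicted genes and pseudogenes. Where none passed, they were the 5 in each direction with a mean of at least 10 CPM and the lowest unadjusted p, given without a verb of change. To these were added up to 4 members of each list with the lowest p, and a panel of Mrc1, Arg1, Vegfa, Spp1, Il1b, Tnf, Nos2, Il10, Cd274, H2-Ab1, Mknk1, Mknk2, Eif4e and Hif1a. The comparisons, tests, gene lists, named gene rule and the alternatives other than those named below as added were fixed before the data were examined. Positions are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and 91.4 percent of the genes tested in polysomes had a symbol in it. Transcript length and GC share were taken from the transcript with the longest coding sequence of each gene.

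Shares of counts per library were compared between size classes with an exact two-sided permutation test over all 1287 splits, for 28 measures, with the same adjustment. Splits within batches were added after the data had been examined, as the mean over the batches of the difference in means, over all 420 splits with the same numbers per batch. The smallest p the first test can give is 0.000777 over all tumours, 0.0476 in batch 1 and 0.100 in batch 2. Alternatives were RLE and upper-quartile scaling, no filter and a mean of at least 10 CPM, non-robust fits, DESeq2 1.42.0, limma voom with quality weights, log2 tumour weight in place of size classes, no batch term, each batch alone, no tumour block, an analysis of partial variance for translation, and leaving out each tumour. Also added after the data had been examined were fits with the transcript length and GC trend removed per library and, for polysome mRNA, with the log2 share of Lars2 as a covariate. Where the length trend is given below as removed, the GC trend was removed with it, so their effects cannot be told apart. Alternatives were run on the counts, the lists, the panel and the genes chosen by fold or p, and single members of a list were refitted only without each tumour. Lists were not tested with DESeq2, voom or the analysis of partial variance.

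The scripts were tested on counts simulated from the libraries' own means and depths, with 100 genes changed by a fold of 2 and 100 by a fold of 4. The changed genes were drawn from those with a mean of at least 10 CPM, so recovery of weaker genes was not measured. The simulated counts held no batch effect, no tumour effect and no correlation between genes, so rates in the real data may differ. For a fold of 2, edgeR recovered 13 percent in total mRNA (11531 genes run), 5 percent in polysome mRNA (10732 genes), 1 percent in translation (11978 genes) and 71 percent in polysome against total mRNA (11975 genes). For a fold of 4 it recovered 82, 67, 59 and 100 percent. In the same simulations 3 of 98, 2 of 74, 4 of 64 and 1 of 172 edgeR calls were false, against 41 of 170, 46 of 151 and 57 of 146 calls of DESeq2 and 1 of 87, 0 of 54 and 2 of 62 calls of voom in the 3 size comparisons, and 5 of 77 calls of the analysis of partial variance in translation. Per-library values and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and sequences were searched with BLAST 2.17.0.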

Results

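Macrophages sorted from 13 mouse mammary tumours were measured as total mRNA and as polysome-associated mRNA, the part of the mRNA that carries at least 3 ribosomes and is taken as engaged in translation. The tumours were 8 small tumours (467 to 841.8 mg) and 5 large tumours (1504 to 2245 mg), which gave 26 libraries. Total counts per library were 18018519 to 48340879 in total mRNA of small tumours and 20418974 to 55609113 in that of large tumours. Polysome libraries were shallower, with 7034173 to 20284077 counts in small tumours and 13045733 to 28257436 in large tumours. Total mRNA libraries had counts for 11850 to 17990 genes and polysome libraries for 10695 to 12334. Apoe, the apolipoprotein E gene, took the most counts in each total mRNA library, and Lars2, the gene of mitochondrial leucyl-tRNA synthetase, took the most in most polysome libraries. The median correlation of a library's log2 CPM with the other libraries of its RNA source was 0.899 for total mRNA and 0.825 for polysomes.

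The first comparison asks which mRNAs of these macrophages were over- or under-represented on polysomes relative to total mRNA of the same tumour. Of 12109 genes tested, 2741 were higher in polysomes and 4116 were lower (edgeR quasi-likelihood test, adjusted p below 0.05). Lars2 (chromosome 9, 123366927 to 123462666) had the largest fold among genes with a mean of at least 10 CPM, 6.02 ± 0.50 on the log2 scale (SE, adjusted p = 7.65e-10), and was higher in 13 of 13 tumours. Its level was 3590 ± 2956 CPM in total mRNA and 121006 ± 82784 CPM in polysomes (SD, n = 13). Its share of total mRNA counts was uneven, at 0.433 to 0.902% in batch 1 and 0.00304 to 0.571% in batch 2. The lowest shares were in small replicates 6 (0.00304%) and 7 (0.00658%) and large replicate 3 (0.00406%). The fold without these tumours together was not fitted. Cebpb, a transcription factor of myeloid cells (chromosome 2, 167688915 to 167690418), was higher by 4.10 ± 0.42 (adjusted p = 1.3e-08) in 12 of 13 tumours, with 66.1 ± 44.3 CPM in polysomes against 15.7 ± 46.3 CPM in total mRNA (SD, n = 13). Without small replicate 8 the level in total mRNA was 2.83 ± 1.01 CPM (SD, n = 12) and the fold 4.37. Asah1, the lysosomal acid ceramidase (chromosome 8, 41340197 to 41374773), was lower by −3.70 ± 0.22 (adjusted p = 1.4e-11) in each of the 13 tumours, from 597 ± 193 to 48.3 ± 23.8 CPM.

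The other genes with the largest folds above 0 were Uhmk1, a kinase that phosphorylates a splicing factor (4.08 ± 0.49), Lrp5, a Wnt co-receptor (3.99 ± 0.48), and Osbp, an oxysterol-binding protein (3.69 ± 0.38). Ppp6r1 (3.60 ± 0.25), Znrf2 (3.52 ± 0.26) and Ldb1 (3.50 ± 0.35) followed. The replication-dependent histone genes Hist2h3b (4.28 ± 0.64), Hist1h2ab (3.50 ± 0.29), Hist1h3c (3.49) and Hist1h2ai (3.48) were also among them. Histone genes have near-identical copies, so their single values are uncertain. At the other end stood Chil3, a chitinase-like marker of alternative activation (chromosome 3, 106147554 to 106167564), at −4.87 ± 0.66 (adjusted p = 1.1e-06; 20.2 ± 22.5 CPM in total mRNA and 1.64 ± 2.45 CPM in polysomes). Pcca, a subunit of propionyl-CoA carboxylase, had −4.30 ± 0.59, the SNARE protein gene Vamp4 −4.16 ± 0.49 (−4.77 without small replicate 1), the G protein-coupled receptor gene Gpr171 −4.03 ± 0.30, the scavenger receptor gene Colec12 −4.00 ± 0.43 and the interferon-induced Ifit3 −3.65 ± 0.47. Aldh1b1, Pyhin1, Arhgap15 and Taf13 lay between −3.72 and −3.58, with Aldh1b1 at −3.11 without large replicate 3, −3.13 without large replicate 5 and −4.33 without large replicate 4. Acta1, skeletal muscle actin, was called at −4.20 ± 1.32 (adjusted p = 0.0192), and this call was lost without large replicate 1 (adjusted p = 0.0532), 2 (0.0519), 3 (0.0557) or 5 (0.0585), with voom (0.0597) and without the tumour block (0.0550).

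Proteasome subunits were lower in polysomes as a group. Of 37 subunits 27 were lower and 3 higher, 29 and 3 when adjusted over the list alone (camera adjusted p = 2.8e-05, and adjusted p = 0.225 with an estimated correlation). Psma1 of the catalytic core had −2.55 ± 0.19, from 281 to 50.7 CPM, and Psmc2 and Psmd14 of the regulatory particle had −2.39 and −2.48. Cell cycle genes followed, with 24 of 32 lower and 3 higher in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.00045, and adjusted p = 0.225 with an estimated correlation). Among them were the replication helicase subunit Mcm6 (−2.97 ± 0.29), the DNA clamp Pcna (−1.67 ± 0.18) and the mitotic cyclin Ccnb1 (−2.04). Unfolded protein response genes and ER chaperones were lower in 13 of 19 and higher in 3 in both counts (camera adjusted p = 0.0072, and adjusted p = 0.225 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, had −2.75 ± 0.20, from 1147 to 202 CPM, while Edem1, which acts in the degradation of misfolded proteins, was higher by 2.25 ± 0.23. Interferon response genes were lower in 14 of 28 and higher in 0 in both counts (camera adjusted p = 0.0311, and adjusted p = 0.225 with an estimated correlation), with the guanylate-binding proteins Gbp3 (−2.75 ± 0.22) and Gbp2 (−2.23) as examples. In batches 1 and 2 alone the median folds were −1.49 and −0.50 for proteasome subunits, −0.99 and −0.87 for cell cycle genes, −0.81 and −1.10 for the unfolded protein response and −0.98 and −0.93 for interferon response genes. The interferon call was lost without the tumour block (adjusted p = 0.122) and with the transcript length and GC trend removed together (0.0981), and the latter also ended the proteasome call (0.0532).

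The other 23 lists were not called in this comparison (camera adjusted p from 0.161 to 0.998), and most held members that went both ways. With no filter on low counts the lists of eIF4E and MNK pathway genes, mRNAs sensitive to eIF4E and immediate early genes were called as higher (camera adjusted p = 0.0264 each). These calls used the preset correlation, as an estimated one was run in the main fit only, where it called 0 lists (lowest adjusted p = 0.225). In the list of eIF4E and MNK pathway genes, which set cap-dependent initiation, 10 of 19 were higher and 7 lower in both counts. The 4E-binding protein Eif4ebp2 had 3.33 ± 0.36, Mknk2, a kinase of eIF4E, 2.31 ± 0.24 (18.7 to 83.0 CPM, 13 of 13 tumours) and the S6 kinase Rps6kb1 −2.61. Of mRNAs named as sensitive to eIF4E, 8 of 21 were higher and 1 lower, with ornithine decarboxylase Odc1 at 2.64 and the survival gene Mcl1 at 1.34. Immediate early genes, which respond first to stimulation, were higher in 11 of 20 and lower in 6, with Jund at 2.35 and Klf2 at 2.07. Nuclear-encoded oxidative phosphorylation genes went both ways, with 20 of 69 higher and 27 lower, Cox6a1 at 1.96 and the succinate dehydrogenase subunit Sdha at −3.23 ± 0.19, and a median of −0.79 in batch 1 and 0.40 in batch 2. Of cytosolic ribosomal proteins 11 of 76 were higher and 21 lower, and the batches went opposite ways, with a negative fold in 72 in batch 1 (median −1.72) and a positive fold in 71 in batch 2 (median 1.54). Their mRNAs took 3.94 ± 0.901% of total and 1.16 ± 0.351% of polysome counts in small tumours of batch 1 (SD, n = 5), and 1.96 ± 1.26% and 5.03 ± 0.597% in those of batch 2 (n = 3). Rps7 had a fold of −4.38 in batch 1 and 0.20 in batch 2, and the difference between batches was not tested. MHC class II and co-stimulation genes were lower in 10 of 15 and higher in 1, and hypoxia and glycolysis genes lower in 16 of 26 and higher in 3. Alternative activation genes were split, 5 higher and 6 lower of 25, or 5 and 5 when adjusted over the list alone, with the transcription factor Maf at 2.20 ± 0.18. Pro-inflammatory genes were split 7 to 9 of 25, with the receptor Cd40 at 2.28 ± 0.22 and Il18 at −1.52. Counts adjusted over the list alone were the same for these lists unless given.

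Among the macrophage genes followed in every comparison, the growth factor Vegfa was higher in polysomes (2.14 ± 0.45) and so was the cytokine Tnf (1.47 ± 0.19), each in 13 of 13 tumours. Osteopontin, Spp1, was lower (−1.95), as were the cap-binding protein Eif4e (−1.67) and the oxygen-regulated Hif1a (−1.50). Also lower were Nos2 (−3.30), Mknk1 (−0.92) and the MHC class II chain H2-Ab1 (−0.83), whose call was lost without the tumour block (adjusted p = 0.132). For Spp1, polysome minus total log2 CPM was lower in each tumour of batch 2 than in any of batch 1. For Eif4e it was lower in each tumour of batch 1 than in any of batch 2. The folds of Spp1 and Eif4e therefore average over unlike batches, and the difference between batches was not tested. The mannose receptor Mrc1 (−0.36, adjusted p = 0.148), arginase Arg1 (−0.68, 0.0622), Il1b (0.075, 0.783), Il10 (−1.78, 0.203) and the checkpoint ligand Cd274 (0.12, 0.816) did not pass. Mrc1 passed without large replicate 2 (adjusted p = 0.0451), and Arg1 without large replicate 2 (0.0409), large replicate 3 (0.0110) or small replicate 7 (0.0369) and with voom (0.00927). The median fold of all tested genes was −0.34, so a fold of that size stands at the middle of the genes, and RLE and upper-quartile scaling moved this median by less than 0.1, to −0.27 and −0.29. Without genes under 10 CPM, 2523 genes were higher and 2903 lower.

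**Figure D1:**
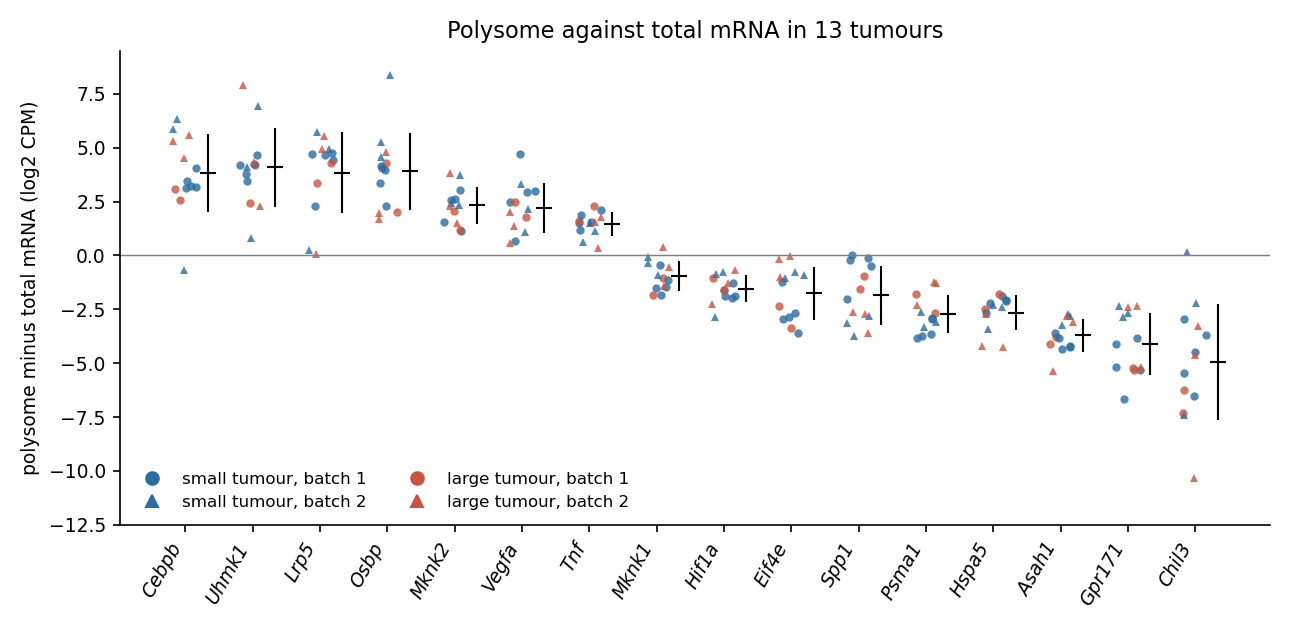
Polysome minus total log2 CPM of 16 genes in each of the 13 tumours (blue small, red large, circles batch 1, triangles batch 2), with a black mark for the mean ± SD. Mknk2, Vegfa and Tnf lie above 0 in 13 of 13 tumours and Asah1 below 0 in each.

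The second comparison asks how total mRNA of the macrophages differed between large and small tumours. When the tumours were regrouped within batches, 93 of 100 groupings, the real one included, gave as many lists as the 5 called here. Chance can therefore not be excluded for these list calls. Immediate early genes, which are induced within minutes of stimulation, were lower as a group in large tumours, with a negative fold in 16 of 20 (median −0.51; camera adjusted p = 0.0018, and adjusted p = 0.800 with an estimated correlation). Examples were the transcription factors Egr3 (−2.13 ± 0.60) and Egr1 (−1.35 ± 0.58; 377 CPM in small and 141 CPM in large tumours, and −2.12 without large replicate 1). Alternative activation genes were higher as a group, with a positive fold in 20 of 25 (median 0.57; camera adjusted p = 0.0055, and adjusted p = 0.800 with an estimated correlation). The hyaluronan receptor Lyve1 had 2.47 ± 0.93, the secreted factor Retnla 2.07 ± 0.79 and Mrc1 1.08 ± 0.62. Without large replicate 3 the folds of Lyve1 and Retnla were 1.44 and 0.76, and without large replicate 1 that of Lyve1 was 3.08. Hypoxia and glycolysis genes had a positive fold in 22 of 26 (median 0.25; camera adjusted p = 0.0084, and adjusted p = 0.800 with an estimated correlation). Pfkfb3, which drives glycolysis, had 0.73 ± 0.29 and the glucose transporter Slc2a1 0.98 ± 0.51, which was 0.084 without large replicate 1. MHC class I presentation genes had a positive fold in 10 of 13 (median 0.26; camera adjusted p = 0.0347, and adjusted p = 0.800 with an estimated correlation), with the peptide transporter Tap2 at 1.19 ± 0.43. Oxidative phosphorylation genes had a negative fold in 55 of 69 (median −0.17; camera adjusted p = 0.0375, and adjusted p = 0.844 with an estimated correlation), with Ndufa5 of complex I at −0.66 ± 0.33.

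No single gene passed the threshold in total mRNA. Of 11671 genes, edgeR called 0 (lowest adjusted p = 0.865), with 538 at an unadjusted p below 0.05 (170 higher and 368 lower in large tumours), against 584 that chance would give, and DESeq2 and voom called 0 as well. Adjusted over the list alone, 0 members passed in each list. Genes with the lowest p and a fold above 0 were Ncoa4, which carries ferritin to its breakdown (0.85 ± 0.22), and the iron exporter Slc40a1 (1.52 ± 0.47; 21.2 ± 13.1 and 60.2 ± 58.4 CPM, or 34.5 ± 13.2 CPM in large tumours without large replicate 1). Next were Heatr1 (1.13 ± 0.33), Ints2 (0.91 ± 0.28) and Ogt, the O-GlcNAc transferase (0.90 ± 0.28). Those with a fold below 0 were the calcineurin regulator Rcan1 (−1.02 ± 0.25; 86.0 ± 26.4 and 47.1 ± 18.6 CPM), Marcksl1, a relative of the actin-binding Marcks (−1.86 ± 0.50). The others were Ei24 (−1.27 ± 0.33), Brf1 (−1.29 ± 0.35) and Mettl9 (−1.27 ± 0.35). In the panel, Spp1 had −0.91 ± 0.37 (4156 CPM in small and 2483 CPM in large tumours). The other folds were Arg1 0.58, Vegfa 0.44, Il1b 0.53, Tnf −0.63, Nos2 2.73, Il10 −0.34, Cd274 0.88, H2-Ab1 −0.034, Mknk1 0.95, Mknk2 0.63, Eif4e 0.11 and Hif1a −0.31, each with an adjusted p of 0.865 or more. Nos2 had 1.67 without large replicate 5 and 3.52 without large replicate 2. Its level was near the floor, at 0.606 ± 0.835 CPM in small and 2.84 ± 3.53 CPM in large tumours.

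Fibroblast markers had a negative fold in 11 of 12 (median −1.39; camera adjusted p = 0.0548), with the matrix proteoglycan Bgn at −3.02 ± 1.07 and the collagen Col1a1 at −2.26 ± 1.01. Without small replicate 7 these folds were −0.73 and −0.53, and without small replicate 1 −2.38 and −1.22. The list was called with upper-quartile scaling (0.0443), no filter (0.0388), a mean of at least 10 CPM (0.0224), no batch term (0.0441) and the transcript length and GC trend removed (0.0413), each at the preset correlation. In the main fit an estimated correlation called 0 of the 27 lists (lowest adjusted p = 0.800). These markers took 0.106 ± 0.163% of total mRNA counts in small and 0.0307 ± 0.0120% in large tumours (exact permutation p = 0.441, and 0.431 over splits within batches). Without small replicate 7 the share in small tumours was 0.0585 ± 0.0992%. The remaining lists had camera adjusted p from 0.0548 to 0.784, and some were called under an alternative. The calls that follow used camera at its preset correlation, as an estimated one was not run under the alternatives. In batch 1 alone pro-inflammatory genes (5.9e-10) and ribosomal proteins (3.77e-05) were lower, and the unfolded protein response (0.00219), lipid (0.0315) and mammary epithelial (0.0317) lists higher. In batch 2 alone the mammary epithelial (0.00120), integrated stress response (0.00120) and eIF4E-sensitive (0.0213) lists were lower and monocyte markers higher (0.00199). Without the batch term ribosomal proteins (9.7e-05) and cell cycle genes (0.0161) were lower and monocyte markers higher (0.00620). With no filter the resident macrophage (0.00300), lipid (0.00434), class II (0.00971), unfolded protein response (0.0112), interferon (0.0143), neutrophil (0.0163) and monocyte (0.0387) lists were higher. At a mean of at least 10 CPM the eIF4E-sensitive (0.0224), cell cycle (0.0268) and integrated stress response (0.0316) lists were lower and resident macrophage markers higher (0.0497). The eIF4E-sensitive list was lower with log2 weight (0.0292), and with the length trend removed cell cycle genes were lower (0.0101) and resident macrophage markers higher (0.0314). Fibroblast markers were lower at a mean of at least 10 CPM (0.0224), with no filter (0.0388), with the length trend removed (0.0413), without the batch term (0.0441) and with upper-quartile scaling (0.0443). The list calls rested in part on single tumours. The immediate early call held without any 1 tumour (adjusted p up to 0.0474). Alternative activation was lost without small replicate 7 (0.158), small replicate 8 (0.0636) or large replicate 3 (0.0880), and in batch 1 alone its direction turned down (0.713), with Mrc1 at −0.095 in batch 1 and 2.05 in batch 2. The hypoxia call was lost without small replicate 1 (0.0774), large replicate 1 (direction down, 0.978) or large replicate 3 (0.0840), and in batch 2 alone (0.930). The class I call was lost without small replicate 1 (0.0774), 5 (0.0512) or 7 (0.0825) or large replicate 1 (0.169) or 4 (0.108), and in batch 1 (0.0785) and batch 2 (0.0985) alone. The oxidative phosphorylation call was lost without small replicate 2 (0.0514), 4 (0.120), 5 (0.0687), 6 (0.116) or 8 (0.429) or large replicate 1 (0.216) or 5 (0.870), and in batch 1 (0.624) and batch 2 (0.167) alone. It was also lost with upper-quartile scaling (0.0598) and with no filter (0.339). With log2 weight in place of size classes the hypoxia (0.0655) and class I (0.0715) calls were lost, and without the batch term the class I call (0.270).

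The third comparison took polysome-associated mRNA of large and small tumours. As many lists as the 8 called here came from 42 of 100 groupings of the tumours within batches, the real one included, so chance cannot be excluded for their number. Nuclear-encoded oxidative phosphorylation genes were higher as a group in large tumours, with a positive fold in 61 of 69 (median 0.53; camera adjusted p = 1.2e-12, and adjusted p = 0.798 with an estimated correlation). Proteasome subunits were too, with 31 of 36 (median 0.57; camera adjusted p = 4.3e-09, and adjusted p = 0.798 with an estimated correlation). The succinate dehydrogenase subunit Sdhb had 1.49 ± 0.31 (78.9 CPM in small and 218 CPM in large tumours; chromosome 4, 140961203 to 140979193) and the complex I subunit Ndufb5 1.43 ± 0.34 (34.6 and 108 CPM). The proteasome core subunit Psmb2 had 1.35 ± 0.29 (69.8 and 187 CPM; chromosome 4, 126677630 to 126709714). Cytosolic ribosomal proteins had a positive fold in 67 of 75 (median 0.39; 1.07e-07, and adjusted p = 0.798 with an estimated correlation), with Rpl19 at 1.04 ± 0.28 and Rpl10 at 1.05 ± 0.28. MHC class II and co-stimulation genes had one in 13 of 15 (median 0.64; 0.00145, and adjusted p = 0.798 with an estimated correlation), with the peptide-loading chains H2-DMb2 (1.71 ± 0.42; chromosome 17, 34143307 to 34151555), H2-DMa (1.49 ± 0.39) and H2-DMb1 (1.18 ± 0.43).

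Lipid handling and lysosome genes also had positive folds in 21 of 25 (median 0.37; camera adjusted p = 0.00318, and adjusted p = 0.798 with an estimated correlation). The lectin Lgals3 had 1.65 ± 0.45, the lysosomal lipase Lipa 0.83 ± 0.30 and the fatty acid binding protein Fabp5 1.28 ± 0.47. Without large replicate 1 Lgals3 had 0.99 and Fabp5 0.62. Resident-type macrophage markers had positive folds in 13 of 15 (median 0.34; 0.0159, and adjusted p = 0.798 with an estimated correlation), with the complement genes C1qa (0.98 ± 0.42) and C1qb (1.03 ± 0.45). They took 2.43 ± 0.892% of polysome counts in small and 2.98 ± 0.660% in large tumours (exact permutation p = 0.296, and 0.164 over splits within batches). Hypoxia and glycolysis genes had positive folds in 19 of 25 (median 0.29; 0.0430, and adjusted p = 0.798 with an estimated correlation), with aldolase Aldoa at 1.06 ± 0.38. Fibroblast markers were lower as a group, negative in 9 of 12 (median −1.70; 0.0353, and adjusted p = 0.798 with an estimated correlation), with the collagen Col3a1 at −3.01 ± 1.00, which was −1.39 without small replicate 7 and −2.41 without small replicate 1. Their share of polysome counts was 0.0670 ± 0.133% in small and 0.0138 ± 0.00997% in large tumours (exact permutation p = 0.633, and 0.326 over splits within batches), and without small replicate 7 it was 0.0205 ± 0.0241% in small tumours. Monocyte markers took 0.257 ± 0.114% and 0.110 ± 0.0366% (exact permutation p = 0.0179, 0.0262 over splits within batches, 0.143 in batch 1 and 0.100 in batch 2, where it is the smallest p possible). Fibronectin, Fn1, had −1.01 ± 0.43, and the list was not called (camera adjusted p = 0.472). Of 28 such shares 0 passed adjustment (lowest adjusted p = 0.283, and 0.133 over splits within batches, a test chosen after the data had been examined).

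At the level of single genes, edgeR called 0 of 10933 in polysomes (lowest adjusted p = 0.0772), with 1362 at an unadjusted p below 0.05 (787 higher and 575 lower in large tumours) against 547 that chance would give. DESeq2 called 152 (92 higher and 60 lower), voom 254 (226 and 28), edgeR without a filter 3 and edgeR with log2 weight 1, and without small replicate 5 edgeR called 42. Adjusted over the list alone, 15 oxidative phosphorylation genes, 13 proteasome subunits, 3 ribosomal proteins, 2 MHC class II genes and 1 lipid and lysosome gene passed as higher, and 0 of the hypoxia, resident macrophage and fibroblast lists. In lists that camera did not call, 2 MHC class I genes, 1 translation factor with a TOP mRNA, 1 mRNA sensitive to eIF4E and 1 dendritic cell marker passed as higher, and 1 MHC class I gene, 1 dendritic cell marker and 1 immediate early gene as lower. Genes with the lowest p and a fold above 0 were Hagh, a glyoxalase that removes methylglyoxal products (2.06 ± 0.35, adjusted p = 0.0772; chromosome 17, 24840143 to 24864450) and the iron exporter Slc40a1 (2.39 ± 0.41, adjusted p = 0.0772; 18.8 ± 13.0 and 79.6 ± 55.7 CPM; chromosome 1, 45908068 to 45926523). Next were the joined row of Nubp1 and Tvp23a (1.31 ± 0.24), the immunoproteasome subunit Psmb9 (1.76 ± 0.33; 29.2 ± 13.9 and 84.6 ± 41.4 CPM) and the ribosomal protein Rpl15 (1.34 ± 0.26), each with an adjusted p of 0.100. Below 0 were Ctdspl (−1.81 ± 0.39, adjusted p = 0.113) and D16Ertd472e (−2.02 ± 0.46, adjusted p = 0.134). At the same adjusted p stood the glycosyltransferase Galnt1 (−1.18 ± 0.27; 207 ± 28.5 and 87.2 ± 34.5 CPM), the actin-binding kinase substrate Marcks (−1.26 ± 0.29; 555 ± 168 and 216 ± 51.8 CPM) and the stress granule protein Tia1 (−1.30 ± 0.31). In the panel, the folds were Mrc1 0.067, Arg1 0.17, Vegfa −0.26, Spp1 −1.04, Il1b 0.46, Tnf −0.081, Il10 −0.54, Cd274 0.79, H2-Ab1 0.64, Mknk1 0.83, Mknk2 0.22, Eif4e 0.36 and Hif1a 0.13, and Nos2 was under the filter.

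The remaining 18 lists had camera adjusted p from 0.175 to 0.977 in polysomes. Of these, in batch 1 alone pro-inflammatory genes (2.64e-07) and monocyte markers (0.000581) were called lower and class I genes higher (0.00678), and in batch 2 alone alternative activation genes higher (0.0106). Like all list calls under an alternative, these used camera at its preset correlation, as an estimated one was not run there. Pro-inflammatory genes were called lower with the length trend removed (0.0158), and with the Lars2 covariate the neutrophil (0.0192), interferon (0.0301), alternative activation (0.0331) and immediate early (0.0344) lists were called higher. Lars2 took 14.6 ± 6.99% of polysome counts in small and 5.79 ± 3.02% in large tumours (exact permutation p = 0.0202, and 0.00476 over splits within batches). The shares were 18.6 ± 5.51% and 7.65 ± 4.03% in batch 1 (exact permutation p = 0.0952) and 7.98 ± 2.06% and 4.55 ± 2.08% in batch 2 (p = 0.100, the smallest possible). With the log2 share of Lars2 as a covariate, chosen after the data had been examined, the calls of oxidative phosphorylation (adjusted p = 0.0674), proteasome (0.177), lipid (0.177), resident macrophage (0.114) and hypoxia (0.157) lists were lost. With the transcript length and GC trend removed together, those of oxidative phosphorylation (0.136), ribosomal proteins (direction down, 0.231), class II (0.0747), fibroblasts (0.0575) and hypoxia (0.0747) were lost. In batch 1 alone the ribosomal protein (0.145) and resident macrophage (0.157) lists were not called, and in batch 2 alone the lipid (0.319), fibroblast (0.549) and hypoxia (0.752) lists were not. Without the batch term the class II (0.0671), lipid (0.0752), resident macrophage (0.208), fibroblast (0.146) and hypoxia (0.199) calls were lost. Without small replicate 7 the lipid (0.0584), resident macrophage (0.468), fibroblast (0.621) and hypoxia (0.0712) calls were lost, and the resident macrophage call also without large replicate 2 (0.187). The fibroblast call was lost as well without small replicate 1 (0.0919), large replicate 1 (0.342) or large replicate 5 (0.0667). The hypoxia call was lost without small replicate 1 (0.187), 2 (0.0577), 3 (0.104), 4 (0.0680) or 8 (0.149) or large replicate 1 (0.896). Upper-quartile scaling ended the fibroblast (0.0650) and hypoxia (0.0554) calls, no filter (0.0952) and log2 weight (0.123) the fibroblast call, and a mean of at least 10 CPM the hypoxia call (0.109).

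**Figure D2:**
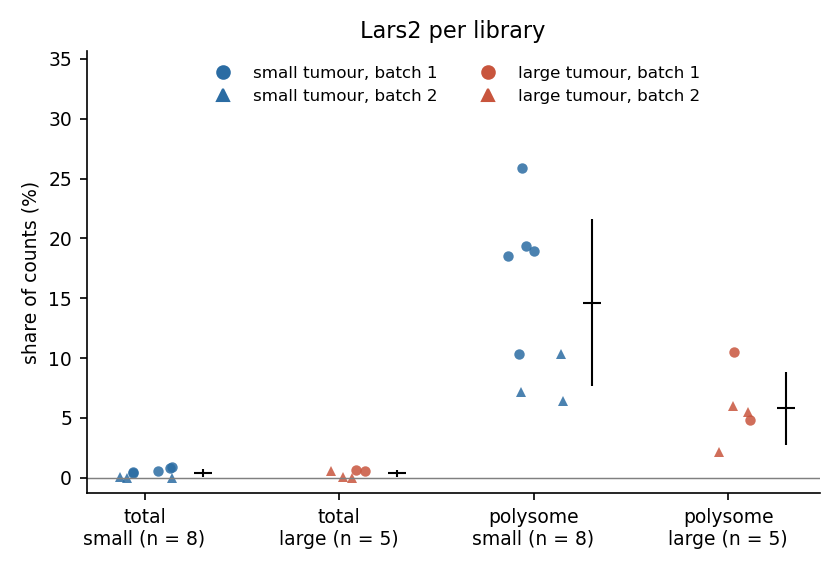
Share of counts taken by Lars2, in percent, in each of the 26 libraries, with the mean ± SD of each group. Polysome libraries of small tumours average 14.6% and those of large tumours 5.79%, while total mRNA libraries average 0.407% and 0.369%. Single total mRNA libraries range from 0.00304 to 0.902%.

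The fourth comparison, of translation, asks whether polysome association relative to total mRNA differed between large and small tumours, as the interaction of RNA source and size. As many lists as the 4 called here came from 19 of 50 groupings of the tumours within batches, the real one included, so chance cannot be excluded for their number. Oxidative phosphorylation genes had a higher polysome association in large tumours as a group, with a positive interaction in 60 of 69 (median 0.61; camera adjusted p = 5.9e-13, and adjusted p = 0.384 with an estimated correlation). For Ndufb5 of complex I (chromosome 3, 32736990 to 32751566), polysome minus total log2 CPM was −2.37 ± 1.05 in small and −0.18 ± 0.94 in large tumours (SD), with an interaction of 1.84 ± 0.39. Ndufs8 had 1.53 ± 0.39, the cytochrome c oxidase subunit Cox5a 1.44 ± 0.37 and the ATP synthase subunit Atp5c1 1.28 ± 0.35. Proteasome subunits were positive in 33 of 37 (median 0.53; camera adjusted p = 6.8e-07, and adjusted p = 0.344 with an estimated correlation). Psmb2 had 1.41 ± 0.36, Psma1 1.31 ± 0.36 and the immunoproteasome subunits Psmb8 and Psmb10 1.20 ± 0.34 and 1.18 ± 0.34. Cytosolic ribosomal proteins were positive in 56 of 76 (median 0.28; camera adjusted p = 0.0088, and adjusted p = 0.882 with an estimated correlation), with Rpl15 at 1.37 ± 0.37. MHC class II genes were positive in 11 of 15 (median 0.49; camera adjusted p = 0.0225, and adjusted p = 0.395 with an estimated correlation), with H2-DMb2 at 1.49 ± 0.37 and H2-Eb1 at 1.15 ± 0.46.

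For single genes the interaction test of edgeR called 0 of 12109 (lowest adjusted p = 0.279), with 1385 at an unadjusted p below 0.05 (747 above and 638 below 0) against 605 that chance would give. DESeq2 called 129 (76 and 53), voom 0, the analysis of partial variance 0 (lowest adjusted p = 0.0515) and edgeR without a filter 8. Adjusted over the list alone, 15 oxidative phosphorylation genes, 9 proteasome subunits and 3 class II genes passed as higher and 0 ribosomal proteins. Genes with the lowest p were, above 0, the glycosyltransferase B4gat1 (3.04 ± 0.62; −5.33 ± 1.68 in small and −1.85 ± 0.99 in large tumours), Commd2 (2.10 ± 0.44; −1.82 ± 0.91 and 0.49 ± 0.56; chromosome 3, 57644349 to 57651715) and Ndufb5. Next were the vesicle adaptor subunit Ap3s1 (2.20 ± 0.47) and the ER membrane selenoprotein gene Selk (1.82 ± 0.42). Below 0 were the signal peptidase subunit Spcs3 (−1.55 ± 0.38), the joined row of Iqcg and Lrch3 (−2.19 ± 0.54) and tripeptidyl peptidase Tpp2 (−1.60 ± 0.40). Atf1 had −1.60 ± 0.41 and Zfp263 −1.94 ± 0.50, these 5 each with an adjusted p of 0.300. Mrc1 had an interaction of −1.35 ± 0.43 (adjusted p = 0.307), with −0.58 in batch 1 and −2.10 in batch 2, and H2-Ab1 0.90. The other panel values were Arg1 −0.39, Vegfa −0.76, Spp1 −0.22, Il1b −0.42, Tnf 0.22, Nos2 4.24, Il10 2.83, Cd274 −0.55, Mknk1 −0.11, Mknk2 −0.43, Eif4e 0.17 and Hif1a 0.24. Without 1 tumour Il10 ranged from 0.95 (small replicate 6) to 4.55 (small replicate 7) and Nos2 from 2.51 (large replicate 1) to 4.83 (small replicate 4). Both genes were near the floor. Il10 had 0.558 ± 1.04 CPM in polysomes of small and 0.656 ± 0.609 CPM in those of large tumours. Nos2 had 0.606 ± 0.835 and 2.84 ± 3.53 CPM in total mRNA and was under the filter in the polysome fit.

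In the lists that camera did not call (23 lists, adjusted p from 0.0873 to 0.894), a few members passed when adjusted over the list alone. Those with a lower association in large tumours were 3 fibroblast markers, among them Col3a1 (−1.80 ± 0.53) and Col1a2 (−2.38 ± 0.71, and −1.78 without large replicate 1), 2 monocyte markers, with the chemokine receptor Ccr2 at −1.56 ± 0.41 and Gda at −1.45 ± 0.39, and 1 gene each of the MHC class I, unfolded protein response, resident macrophage and dendritic cell lists. Those with a higher association were 2 MHC class I genes, 2 resident macrophage markers, 1 lipid and lysosome gene and 1 mRNA sensitive to eIF4E. In the latter list Cdk4, a cell cycle kinase, stood at 1.23 ± 0.36. For this list fry gave an adjusted p of 0.0456 where camera gave 0.223, with a positive interaction in 12 of 21. The ribosomal protein call was lost without small replicate 3 (0.124), 4 (0.0681) or 8 (0.852) or large replicate 1 (0.163) or 3 (0.250), and the class II call without large replicate 2 (0.0847) or 5 (0.0866). In batch 2 alone the proteasome (0.0880), ribosomal protein (0.290) and class II (0.290) lists were not called, while the oxidative phosphorylation list was called in each batch (0.00064 and 5.16e-10). With the length and GC trend removed together the ribosomal protein (direction down, 0.446) and class II (0.446) calls were lost and the oxidative phosphorylation (0.00276) and proteasome (0.00556) calls held. At a mean of at least 10 CPM the ribosomal protein (0.0572) and class II (0.0563) calls were lost, and without the tumour block the class II call (0.355). Further lists were called under an alternative by camera at its preset correlation, as an estimated one was not run there. They were the lipid list, higher in batch 1 alone (0.00341) and with log2 weight (0.0425), and immediate early genes, higher with log2 weight (0.0247) and in batch 2 alone (0.0445). Fibroblast markers were called lower at a mean of at least 10 CPM (0.00714) and in batch 1 alone (0.0149), mammary epithelial markers lower with the length trend removed (0.0347) and in batch 1 alone (0.0463), and pro-inflammatory genes lower with the length trend removed (0.0265).

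**Figure D3:**
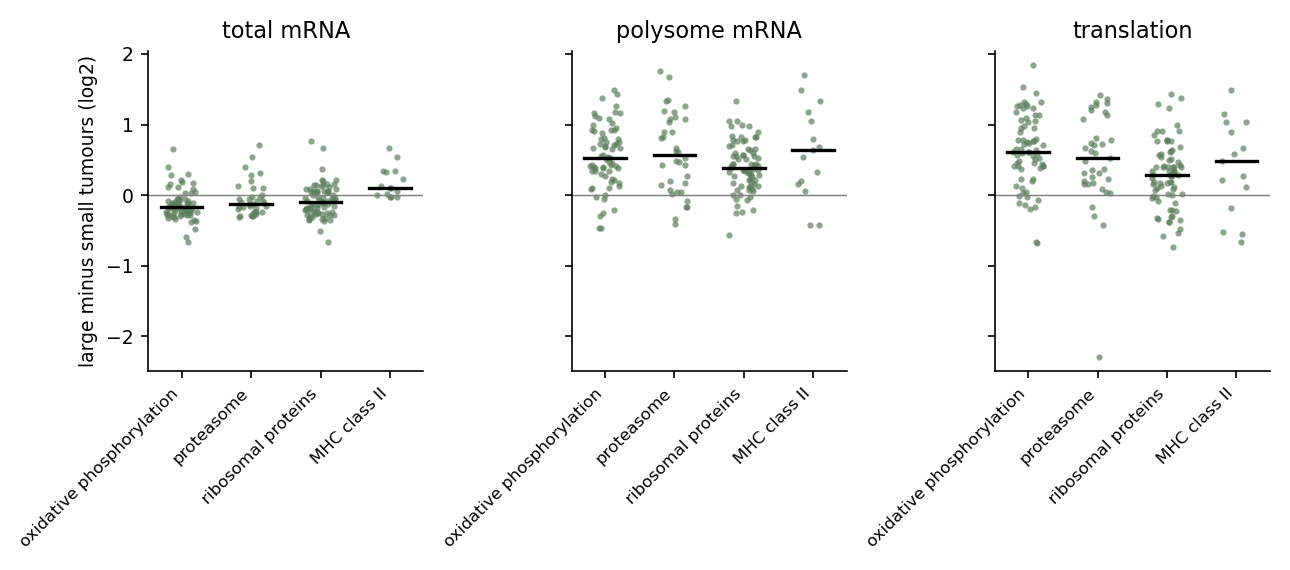
Log2 fold of large against small tumours for the members of each list in total mRNA, in polysome mRNA and in translation, with points for genes and a bar for the median. Oxidative phosphorylation genes have a median of −0.17 in total mRNA, 0.53 in polysome mRNA and 0.61 in translation.

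Folds between large and small tumours followed transcript length in polysomes. Across genes, Spearman's rho with length was −0.419 in polysome mRNA, 0.115 in total mRNA and −0.393 for the interaction, where genes are not independent replicates. In polysomes the genes up to the lower quartile of length had a median fold of 0.38 and those above the upper quartile −0.36. Within batches the polysome rho was −0.165 in batch 1 and −0.448 in batch 2, and that of the interaction −0.132 and −0.391. With coding length in place of transcript length the polysome rho was −0.368, or −0.0502 in batch 1 and −0.466 in batch 2, and that of the interaction −0.355, or −0.0648 and −0.391. Per library, rho with length was taken for the deviation of log2 CPM from the mean of its RNA source and batch. It was 0.101 ± 0.161 in polysomes of small tumours (n = 8) and −0.193 ± 0.0978 in those of large tumours (n = 5). These values are relative to the batch, so opposite signs of the groups arise in part by construction. Within batches the groups differed by −0.298 (exact permutation over 420 splits, two-sided p = 0.0190). The comparison with length and this test were added after the data had been examined. The test uses the same libraries as the folds, so it restates the trend and is not separate support. In total mRNA the values were −0.0427 ± 0.179 and 0.0369 ± 0.211 (exact permutation p = 0.536).

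**Figure D4:**
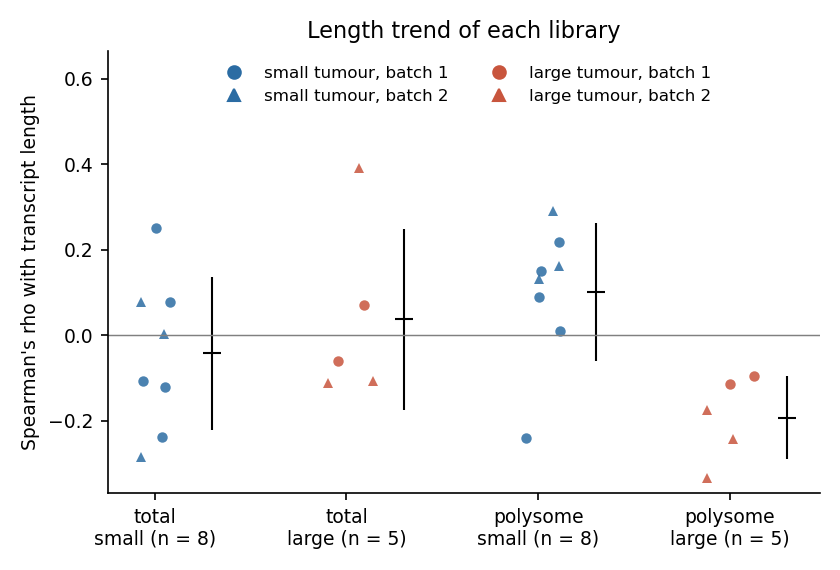
Spearman's rho with transcript length of each library's deviation in log2 CPM from the mean of its RNA source and batch, by RNA source and size class, with the mean ± SD of each group. In polysomes, 5 of 5 large tumours lie below 0 and 7 of 8 small tumours above 0. Each value is relative to the mean of its batch, so opposite signs arise in part by construction.

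Batch 2 was also compared alone, as 3 LR tumours, which are the large ones, against 3 ER tumours. Oxidative phosphorylation genes were higher in polysomes of LR tumours (camera adjusted p = 3.6e-16), as were ribosomal proteins (2.92e-10), MHC class II genes (0.00362) and proteasome subunits (0.0175), with camera at its preset correlation, as an estimated correlation was not run within a batch. For single genes edgeR called 0 of 11859 in total mRNA, 0 of 11086 in polysome mRNA and 0 of 12081 in translation (lowest adjusted p = 0.734, 0.216 and 0.217). The counts at an unadjusted p below 0.05 were 621 (247 higher and 374 lower), 1697 (783 and 914) and 1530 (737 and 793), and DESeq2 called 111, 433 and 383. Without small replicate 7 edgeR called 136 genes in polysomes, and without small replicate 8 it called 12 in translation. In batch 1 alone edgeR called 0 in each comparison, with 346, 580 and 503 genes at an unadjusted p below 0.05. A size by batch term was called for 0 genes in each comparison, with 735, 655 and 904 at an unadjusted p below 0.05.

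Fold changes of large against small tumours in total mRNA and in polysome mRNA were compared across 10867 genes. Pearson's r was 0.307 and Spearman's rho 0.157 across genes, which are not independent replicates, and 52.6% of genes had the same sign in both. Over the 8006 genes with a mean of at least 10 CPM, r was 0.213, rho 0.0615 and the share with the same sign 49.8%. In batch 1 alone r was 0.399 and in batch 2 alone 0.212, and without small replicate 7 it was 0.0972.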

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

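The tests on small replicate 7 were chosen only after its values had been seen. Each value here belongs to 1 tumour that lies farther from the others of its group than Dixon's test at its 95% critical value allows. Of 206 groups of values tested 32 did so. Chance picks about 1 in 20 groups, or 10, where values are normally distributed. CPM and shares of counts were used without a log scale and the groups share tumours, so the excess over 10 is no test against chance. The 32 values came from 9 tumours, with 12 from small replicate 7, 5 from large replicate 1, 3 each from large replicates 2, 3 and 5 and small replicate 6, and 1 each from small replicates 3, 5 and 8.

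Small replicate 7 had the lowest median correlation with the other libraries of its source among small tumours, 0.753 in total mRNA (next 0.862) and 0.708 in polysomes (next 0.802). Fibroblast markers took 0.393% of its polysome counts (next highest 0.0746%). In its total mRNA the matrix genes Dcn (1458 CPM) and Bgn (706 CPM, next 209) lay above each other tumour, while Col3a1 at 307 CPM lay below the highest other (1045 CPM). Mammary epithelial and tumour cell markers took 0.657% of its total mRNA counts (next 0.403%), and resident-type macrophage markers 1.07%, the lowest (next 2.37%). Mast cell and eosinophil markers took 0.00863% of total (next 0.00312%) and 0.00167% of polysome counts (next 0.000797%), and erythroid markers 0.00176% of polysome counts (next 0.000243%). Its polysome library also held the highest values of Ctdspl (76.0 CPM, next 39.6), D16Ertd472e (144 CPM, next 29.7), Tia1 (98.2 CPM, next 53.0) and the cytokine Il10 (2.92 CPM, next 1.19), all higher than in each other small tumour.

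Fibroblast RNA in the sorted cells is a candidate explanation for small replicate 7 that stays open, as does a difference in that tumour's own cell makeup, and size class was not tested as an explanation within 1 tumour. Its depth of 16.4 M counts in polysomes, above the median of the other polysome libraries, argues against shallow sequencing. Fibroblast markers took 0.439% of its total mRNA counts, against 0.282% in the next highest of all tumours, which restates the pattern and does not test it, and a complete sort for CD11b and F4/80 would remove these cells. Of 14 such markers 7 lay above each other tumour and 3 below the median of the others, Fap (1.51 CPM, median 8.03), Thy1 (0.124 CPM, median 0.275) and Mfap5 (0 CPM, median 0.0200). Of 8 lists of other cell types 6 lay above the median of the other tumours in its total library, while dendritic cell markers stood at 0.529 times it, which argues against a lower macrophage share that raised each other type alike.

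Large replicate 1 was the highest of the large tumours for T and NK cell markers, with 0.0226% of total mRNA counts (next 0.00805%) and 0.0121% of polysome counts (next 0.00523%), and for Slc40a1 in total mRNA (163 CPM, next 49.0). In polysomes it was also the highest for Galnt1 (147 CPM, next 80.3) and H2-Ab1 (4621 CPM, next 1654). Large replicate 2 was the highest in polysomes for dendritic cell markers (0.175%, next 0.0841%) and Mrc1 (922 CPM, next 236) and the lowest for Mknk1 (24.7 CPM, next 43.0). Large replicate 3 had the lowest median correlation of large tumours in total mRNA (0.869, next 0.914), the highest Hif1a there (432 CPM, next 241) and the lowest polysome minus total log2 CPM of H2-Ab1 (−1.99, next −0.40). Large replicate 5 was the highest for erythroid markers, with 0.00139% of total mRNA counts (next 0.000271%) and 0.000706% of polysome counts (next 0.000207%), and for Marcksl1 in total mRNA (203 CPM, next 61.3).

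Small replicate 6 was the highest of the small tumours for Rcan1 (144 CPM, next 91.8) and Marcksl1 (921 CPM, next 428) in total mRNA and for Hagh in polysomes (20.2 CPM, next 12.9). Arg1 in total mRNA was highest in small replicate 5 (464 CPM, next 145), Hif1a in total mRNA in small replicate 8 (673 CPM, next 305), and H2-Ab1 in polysomes in small replicate 3 (4194 CPM, next 1891).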

How the results depend on the processing

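Alternatives added after the data had been examined were the removal of the transcript length and GC trend per library, the Lars2 share as a covariate in polysome mRNA and splits within batches for the shares of counts. Of these shares 0 passed over splits within batches and without any 1 tumour. In each batch alone 0 passed as well, which is no test of robustness. The smallest p possible in batch 2 lies above the threshold. In batch 1 a share could pass adjustment only if nearly every share reached the smallest p possible there. Over all alternatives and the fits without 1 tumour, the panel and the genes chosen by fold or p kept their direction and their side of the threshold in 811 of the fits for polysome against total mRNA, 522 for polysome mRNA, 566 for total mRNA and 585 for translation. They turned direction in 7, 40, 30 and 16, passed in 6, 29, 0 and 16 and lost a call in 7, 0, 0 and 0, and those that turned were panel genes that had not passed. List members are not in these counts. Some turned without 1 tumour, such as Cebpb in total mRNA (−2.11, and 0.21 without small replicate 8) and Kit in polysome mRNA (−0.50, and 1.74 without small replicate 7). In polysome against total mRNA, Plvap, S100a8, Cd3e, Krt14, Cma1, Cd4 and Pecam1 lost their call in some of these fits, and Flt1 gained one. The cause was not tested for any of the values that follow. With 5 large tumours, edgeR recovered few genes of a fold of 2 in the size comparisons at these depths.

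Counts of genes were 0 for each size comparison. In polysome mRNA they became 3 with no filter, 152 with DESeq2, 254 with voom and 1 with log2 weight, and in translation 8 with no filter, 129 with DESeq2 and 1, Commd2 (adjusted p = 0.0445), with the length trend removed. In batch 2 DESeq2 called 111 in total mRNA, 433 in polysome mRNA and 383 in translation, and no filter 16 in translation. Whether replicate numbers in the titles of batch 2 pair ER and LR tumours cannot be told. Equal numbers had correlations of 0.204, −0.0198 and 0.367 in total mRNA and −0.0316, 0.0387 and 0.0444 in polysomes. Unequal numbers had −0.371 to 0.145 and −0.0807 to 0.0718. A replicate block on the numbers gave 0, 0 and 0 calls. No tumour block gave 6266 calls for polysome against total mRNA.

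Lists called in total mRNA numbered 12 with no filter, 10 at 10 CPM or more, 8 with no batch term and 8 with the length trend removed. In polysome mRNA they numbered 3 with no batch term and 4 with the length trend removed, in translation 7 in batch 1 and 2 in batch 2 alone, and in polysome against total mRNA 7 with no filter and 2 with the length trend removed. An estimated correlation left 0 lists in each comparison, and fry called 0 in total mRNA, 0 in polysome mRNA, 2 in translation and 20 in polysome against total mRNA. The correlation of total and polysome folds was 0.199 with fits at 10 CPM or more, 0.0688 with voom, 0.399 in batch 1, 0.212 in batch 2 and 0.213 over genes of at least 10 CPM.

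Without 1 tumour at a time, calls ranged from 0 to 0 in total mRNA, 0 to 42 in polysome mRNA (without small replicate 5), 0 to 0 in translation and 6364 to 6834 in polysome against total mRNA. In batch 2 they ranged from 0 to 0, 0 to 136 (without small replicate 7) and 0 to 12 (without small replicate 8). Lists ranged from 3 (without small replicate 1) to 12 (without small replicate 3) in total mRNA, 5 (without small replicate 7) to 9 in polysome mRNA, 3 (without large replicate 1) to 5 in translation and 4 to 4 in polysome against total mRNA. The correlation ranged from 0.0972 (without small replicate 7) to 0.436 (without small replicate 6).

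In batch 1 alone, log2 folds were in total mRNA Mrc1 −0.095, Arg1 −1.92, Il1b −0.53 and H2-Ab1 0.56, in polysome mRNA Mrc1 −0.24, Arg1 −1.31, Vegfa 0.53, Il1b −0.13, Mknk1 −0.10 and Eif4e −0.25, and in translation Arg1 0.70, Il1b 0.033, Cd274 0.53 and Eif4e −0.18. In batch 2 alone they were in total mRNA Vegfa −0.019 and Il10 0.54, in polysome mRNA Tnf 0.39, Il10 0.043, Cd274 −0.31 and Hif1a −0.16, and in translation Spp1 0.23. With voom they were in total mRNA Arg1 −0.92, Il1b −0.66 and Nos2 −1.02, in polysome mRNA Mrc1 −0.50, Il10 1.88 and Cd274 −0.062, and in polysome against total mRNA Il1b −0.024. The analysis of partial variance gave in translation Spp1 0.38, Cd274 0.063, Mknk1 0.22 and Mknk2 0.16. No batch term gave in total mRNA Arg1 −0.89 and Il1b −0.082, and in polysome mRNA Mrc1 −0.42 and Il10 0.28. Log2 weight, whose values are slopes per doubling of tumour weight, gave Il10 0.066 in total mRNA and Tnf 0.0065 in polysome mRNA. With no filter H2-Ab1 had 0.0049 in total mRNA, and with upper-quartile scaling Mrc1 had −0.034 in polysome mRNA. The Lars2 share gave in polysome mRNA Mrc1 −0.00857, Tnf 0.42 and Il10 0.36. Removing the length trend gave in total mRNA H2-Ab1 0.077 and Eif4e −0.039, in polysome mRNA Arg1 −0.11, in translation Tnf −0.12, and in polysome against total mRNA Arg1 0.12. No replicate block gave Il10 −0.32 in translation and Il1b −0.10 in polysome against total mRNA.

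Without 1 tumour at a time, folds of panel genes that turned ranged in total mRNA from −0.20 to 1.40 for Arg1, −0.0051 to 0.22 for Eif4e, −0.80 to 0.31 for H2-Ab1, −0.48 to 0.11 for Hif1a, −0.77 to 0.19 for Il10, −0.94 to 0.17 for Tnf and −0.23 to 0.70 for Vegfa. In polysome mRNA they ranged from −0.44 to 0.69 for Arg1, −0.38 to 1.03 for Cd274, −0.055 to 0.20 for Hif1a, −0.019 to 0.40 for Mknk2, −0.42 to 0.43 for Mrc1, −0.46 to 0.32 for Tnf and −1.26 to 0.18 for Vegfa. In translation they ranged from −0.84 to 0.25 for Arg1, −0.039 to 0.46 for Hif1a, −0.32 to 0.14 for Mknk1 and −0.36 to 0.0098 for Spp1, and in polysome against total mRNA from −0.081 to 0.35 for Cd274 and −0.064 to 0.28 for Il1b.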

Other observations

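Among gene families formed by symbol after the data had been examined (18 families), histone genes were the group with the largest median above 0 in polysomes against total mRNA. Of 66 histone genes 54 were higher and 4 lower (median 2.39; camera adjusted p = 2.3e-21, and adjusted p = 0.178 with an estimated correlation). Their mRNAs mostly lack a poly(A) tail, and near-identical copies make single values uncertain. All 8 subunits of CCT, the chaperonin that folds actin and tubulin, were lower (median −2.10; 2.9e-06, and adjusted p = 0.0557 with an estimated correlation). Of 11 guanylate-binding proteins, which act in defence inside infected cells, 10 were lower (median −2.75; 0.00015, and adjusted p = 0.0557 with an estimated correlation). Lysine demethylases and methyltransferases, which act on chromatin, were higher in 12 of 21 and lower in 2 (median 0.87; 0.0044, and adjusted p = 0.342 with an estimated correlation). Subunits of the vacuolar ATPase, which acidifies lysosomes, were lower in 12 of 22 (median −0.60; 0.0282, and adjusted p = 0.297 with an estimated correlation).

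Mitochondrial ribosomal proteins went with the oxidative phosphorylation list between tumour sizes. The families were tested in the main fits only, without removal of the length and GC trend. Transcript length, which the folds followed in polysomes, was therefore not tested apart from them. Their polysome association was higher in large tumours as a group, with a positive interaction in 64 of 73 (median 0.64; camera adjusted p = 2.8e-11, and adjusted p = 0.240 with an estimated correlation). Polysome mRNA had a positive fold in 63 of 73 (median 0.60; 2.8e-10, and adjusted p = 0.305 with an estimated correlation). In total mRNA 16 of 73 had a positive fold (median −0.15; 0.0912). Lysine demethylases and methyltransferases stood on the other side, with a positive interaction in 2 of 21 (median −0.82; 0.00013, and adjusted p = 0.403 with an estimated correlation). The hnRNP genes, which package nuclear RNA, were lower in polysomes of large tumours as a group, with a positive fold in 5 of 20 (median −0.54; 0.000266, and adjusted p = 0.305 with an estimated correlation). Ribosomal protein mRNAs took 1.16 ± 0.351% of polysome counts in small and 1.22 ± 0.456% in large tumours of batch 1, and 5.03 ± 0.597% and 6.18 ± 0.320% in those of batch 2.

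Of the tests that follow, the bound for the Lars2 share, the splits for the oxidative phosphorylation and proteasome lists and those for the correlation of folds were set before their results were seen. The other tests, and the use of fits that remove the length trend or add the Lars2 share, were chosen only after the data had been examined. Folds of large against small tumours in polysomes fell with transcript length (rho −0.419), while the oxidative phosphorylation and proteasome lists, whose mRNAs are mostly short, were higher. The rho of 0.115 in total mRNA argues against a length or RNA quality bias shared by both libraries of a tumour. The weakest rho without 1 tumour, −0.363, argues against a single library, while a difference between batches stays open, with a rho in batch 1 of −0.165 with transcript length and −0.0502 with coding length. With the length and GC trend removed together both lists kept a camera adjusted p of at most 0.00556 in translation. In polysome mRNA the oxidative phosphorylation call was lost (0.136) and the proteasome call held (0.00891). These values used the preset correlation, which does not measure the spread between tumours, and an estimated one was not run there. Length as the whole cause of both lists therefore stays open. A length bias that arises in polysome libraries alone stays open, as does the share of Lars2, with which as a covariate the rho was −0.219, so that tumour size may go with the polysome association of short mRNAs only as a hypothesis.

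Lars2 took 11.2 ± 7.18% of polysome counts against 0.392 ± 0.324% (range 0.00304 to 0.902%) of total mRNA counts. In polysomes it took 14.6 ± 6.99% in small and 5.79 ± 3.02% in large tumours. Reads of ribosomal RNA counted for Lars2 could give such a share in the ribosome-rich fraction. Its transcripts had 0 matches among 363 annotated transcripts that carry ribosomal RNA (BLAST e-value limit 1e-05), which leaves this open, because that set may lack parts of the large ribosomal RNAs. A higher polysome association of the Lars2 mRNA itself was not tested apart from it.

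Other splits of the tumours, drawn within batches with the same numbers per batch, were fitted for each comparison, and counts of splits include the real one. Where the real count is 0, each split reaches it by construction, so such a count of splits says nothing of chance. In total mRNA, 48 of 100 splits had as many genes at an unadjusted p below 0.05 as the real 538 (highest other 2372). As many as the 5 lists called came from 93 of 100 (highest other 16), so chance cannot be excluded for these, and the 0 genes called were reached by 100 of 100 (highest other 10). The 5 splits with over 3 times the real count put small replicate 8 and large replicates 4 and 5 on one side and the other batch 2 tumours on the other, which points to a structure of the samples, found in these splits and not tested apart from them. In polysomes 3 of 100 splits reached the real 1362 genes (highest other 1760), a share under 0.05. As many as the 8 lists called came from 42 of 100 (highest other 13), for which chance cannot be excluded, and 100 of 100 reached the 0 genes called (highest other 0). The split with 1760 genes put small replicates 1, 4, 6, 7 and 8 together, near the mirror of the real split in batch 2. For the polysome length trend 4 of 100 splits were as strong as −0.419 (highest other 0.491) and for the proteasome list 2 of 100 had a camera p as low as 3.33e-10 (highest other 4.13e-14). Such shares under 0.05 were not adjusted over the patterns tested, most of these tests were chosen after the data had been examined, and other splits gave stronger values. They do not exclude chance. For the oxidative phosphorylation list 10 of 100 had a camera p as low as 4.66e-14 (highest other 1.19e-19), so chance cannot be excluded there either.

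In translation 5 of 50 splits reached 1385 genes at an unadjusted p below 0.05 (highest other 1990), 19 of 50 the 4 lists called (highest other 6) and 3 of 50 the p of 2.18e-14 of the oxidative phosphorylation list (highest other 4.16e-16), so chance cannot be excluded for these. The 0 genes called were reached by 50 of 50 (highest other 10). The length trend of −0.393 was reached by 2 of 50 (highest other −0.424). The camera p of 5.02e-08 of the proteasome list was reached by 1 of 50, the real one (highest other 2.62e-05). These shares are under 0.05 but were not adjusted over the patterns tested, so they do not exclude chance. For polysome against total mRNA, splits that swap the RNA source within tumours gave as many as 6857 genes in 1 of 50, the real one (highest other 1), which argues against chance. As many as 4 lists came from 22 of 50 (highest other 11), for which chance cannot be excluded. The correlation of 0.307 between total and polysome folds was reached by 70 of 100 splits (highest other 0.581), so chance cannot be excluded. In batch 2 alone there are 10 splits, too few for a share under 0.05. The 0 genes called there were reached by 10, 10 and 10 of them in total mRNA, polysome mRNA and translation (highest other 32, 1 and 49). As many at an unadjusted p below 0.05 as the real 621, 1697 and 1530 came from 3, 1 and 2 (highest other 2857, 637 and 2145).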
